A study of Triticum aestivum with 4 samples.

How the data were processed

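Total RNA of young spikes of bread wheat, 3 to 10 mm long, was extracted, amplified, labelled with Cy3 and hybridised to one-colour Agilent oligonucleotide arrays, per the labels' protocols. There were 4 arrays, 2 of Chinese Spring and 2 of the pistillody line, and groups and replicate numbers were taken from the sample titles. Each array's file is the output of Agilent Feature Extraction 9.5 (per the submitters' processing notes; 9.5.1.1 per the file headers), with 39243 spots, of which 37826 are probes, each printed once, and 1417 are control spots. Per the file headers, all 4 arrays lie on 1 slide and were scanned together, so slide and scan could not be batches. The arrays lie at positions 1 and 3 (Chinese Spring replicates 1 and 2) and 2 and 4 (pistillody replicates 1 and 2).

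The values used are the processed signal intensity deposited by the authors. Per the file headers, the software removed spatial and multiplicative trends within each array and replaced signals too close to background by a small surrogate value. A normalization between arrays is not given in the sources used here for the deposited intensity. The series' value table holds the same numbers: 0 of its 156972 values differed from the processed signal of the matching scanner file, so it is on a linear scale, not centred and not normalized, with column medians of 253 and 275 for Chinese Spring and 292 and 279 for the pistillody line. The mean and background intensities of each spot, deposited in the same files, were used only for an alternative background correction. The flags in the files mark spots well above background, saturated spots and outliers.

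From these, the log2 of each probe's signal was taken and the log2 of the array's 75th percentile over all probes was subtracted. Control spots and 29 probes with an outlier flag on any array were left out. A probe was tested if it was well above background on both arrays of at least 1 line, which kept 30177 probes and left out 7620 as dim. Saturation affected 1 probe on 1 array, which was kept. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), on all 4 arrays with the line as the only term, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Fold changes are pistillody line over Chinese Spring. No counting depth exists for arrays. The signal over background and the number of arrays limit the precision. For probes not well above background on any array of a line, a fold is given as a lower bound, from the mean of the bright line and the mean, over the dim line's arrays, of the higher of the probe's own value and the lowest value of any probe well above background on that array.

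The test, the samples, the alternatives, 33 gene lists defined by keywords in gene descriptions, a comparison of genes on the long and short arms of chromosome 7B, and a rule for naming genes were fixed before the data were examined. The gene lists and the chromosome arms could not be used, because all probe descriptions read "Unknown", 0 probes have a chromosome position and 0 probe names occur among the identifiers of the 155467 genes of the reference table of the wheat assembly IWGSC CS RefSeq v2.1. Probe sequences and a genome were not used here. The rule was to name the 12 probes with the largest change in each direction among those past the threshold, with the values of the lines not overlapping and with a described product. Since no product is described, no probe meets it. Instead 2 probes in each direction are given by the same ranking among probes well above background on all 4 arrays, with the condition on the product left out, a choice made after the values were seen. Gene symbols stand in the files for 6 probes, and these are all reported.

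Groups of probes by the beginning of their names, without an r that precedes wh, chosen after the files were seen, took the place of the gene lists. The meaning of these beginnings is not given in the sources used here. Groups of at least 50 tested probes were tested with limma's camera (preset correlation 0.01, and an estimated one) and fry. Pairs of probes whose names differ only by a leading r, or only in p or m near the end, were compared by the Pearson correlation of their changes, with intervals from 2000 bootstrap resamples and p-values from 10000 permutations, two-sided.

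The fit was tested on simulated data. Arrays were drawn for 30198 probes with the mean brightness of the real ones. The spread was drawn from limma's own fitted model, independently for each probe. For each of the known folds, 50 probes were changed in the comparison of 2 arrays against 2. The fit recovered 28% of changes of 1.25-fold, 72% of 1.5-fold, 92% of 2-fold and 96% of 4-fold, and called 3 of 29998 unchanged probes. Most simulated probes were unchanged, whereas 63.4% of the tested probes were called changed in the data, so these rates need not hold there. Among 41 simulated groups, camera called the 1 group that was shifted by 0.3 on the log2 scale and no other. The medians of the real groups lay closer together, between -0.12 and 0.14, and the simulated probes varied independently. The simulation therefore does not give the power of camera in the data.

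The alternatives were quantile normalization, scaling by the median, normexp background correction (offset 50) with either scaling, the authors' value table, no filter on dim probes, a filter for probes well above background on all 4 arrays, eBayes without trend or with robust estimation, a replicate block, and leaving out each array in turn. Keeping flagged spots and a block for the position of the array on the slide were added after the data were seen.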

Results

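Gene expression was measured in young spikes of 2 lines of bread wheat (Triticum aestivum) of the cultivar Chinese Spring, the standard reference cultivar of wheat genetics. The pistillody line carries the cytoplasm of the wild relative Aegilops crassa in place of its own, and its chromosome 7B is present only as the short arm (ditelosomic 7BS), so that the long arm is missing. In pistillody, organs in the position of stamens develop as pistil-like structures. The normal line was Chinese Spring itself. Spikes were 3 to 10 mm long, a stage at which florets were forming, and plants grew in a field. Each line was represented by 2 one-colour oligonucleotide arrays with 37826 probes, each hybridised with Cy3-labelled RNA of 1 sample, and the 4 arrays shared 1 slide.

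Between 29404 and 31589 of the 37826 probes were well above background on each array. The 75th percentile of probe signal lay at 1998 and 2170 units for Chinese Spring replicates 1 and 2, and at 2280 and 2180 units for the pistillody line. The number of arrays limits the precision of every value below. The arrays of 1 line were close to each other, with a Pearson correlation over probes of 0.998 within Chinese Spring and 0.998 within the pistillody line, against 0.967 to 0.968 between the lines. The median absolute log2 difference between replicates was 0.089 in Chinese Spring and 0.056 in the pistillody line, whereas it was 0.27 between the means of the 2 lines. The submitters describe independent experiments but not how separate their plants were, so the p-values measure only the spread between these samples, which may be technical.

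The single comparison of the design asked which transcripts of the young spike differ between the pistillody line and normal Chinese Spring. Of the 30177 probes tested, 19137 (63.4%) changed at an adjusted p under 0.05 in limma (Benjamini-Hochberg over all tested probes). Of these, 10095 were higher and 9042 were lower in the pistillody line. Most of these differences were small: the median absolute log2 difference of the changed probes was 0.41, and 2559 of them (8.48% of those tested) differed at least 2-fold, 901 upwards and 1658 downwards. Under another background correction (normexp with an offset of 50), 1393 probes changed at least 2-fold. All values of the 2 lines were separated in 82.2% of the tested probes, where chance alone separates 33.3% for 2 arrays against 2. In 2074 probes both pistillody arrays lay at least 2-fold from both Chinese Spring arrays, 672 above and 1402 below, and under normexp 1211 probes were so separated.

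Large decreases outnumbered large increases in the pistillody line, and more so as the difference grew. At 4-fold or more, 633 probes were lower and 208 were higher, a ratio of 3.04. At 16-fold or more, 176 were lower and 29 were higher. At 64-fold or more, 55 were lower and 2 were higher. These counts use fitted values, and some of the probes had no signal well above background in 1 of the lines. With such probes set to the lowest fold that their background allows, 499 were lower and 157 higher at 4-fold, 109 lower and 16 higher at 16-fold, and 32 lower and 2 higher at 64-fold. Among the 28532 probes well above background on all 4 arrays, 299 were lower and 117 higher at 4-fold in limma's fit. Under normexp with the 75th percentile, 258 of the tested probes were lower and 76 higher at 4-fold.

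**Figure D1:**
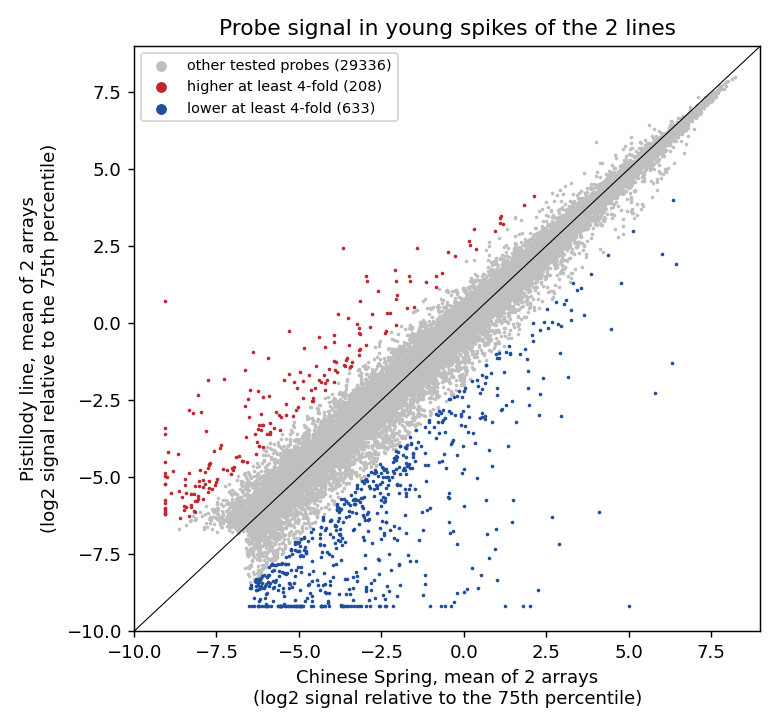
Mean log2 signal of each of the tested probes in Chinese Spring (horizontal axis) and the pistillody line (vertical axis), relative to the 75th percentile of each array, n = 2 arrays per line. The 633 probes at least 4-fold lower (blue) lie below the diagonal of equal signal and the 208 at least 4-fold higher (red) lie above it. Points in a row at the lowest values of an axis are not above background there.

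**Figure D2:**
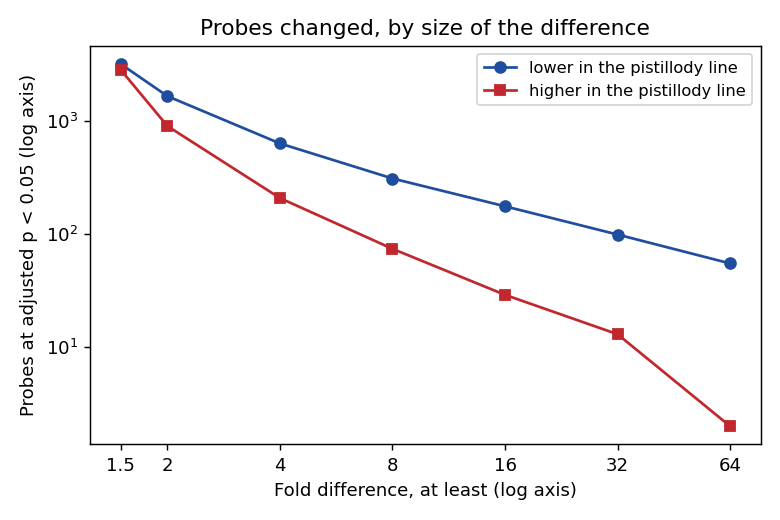
Number of probes with an adjusted p under 0.05 (vertical log axis) that were lower (circles) or higher (squares) in the pistillody line by at least the fold on the horizontal log axis. The 2 lines of points lie near each other at 1.5-fold, with 3190 lower and 2832 higher, and at 64-fold stand at 55 lower and 2 higher, or at 32 and 2 with probes not above background in 1 line at their lowest possible fold (not drawn).

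The files describe the product of none of the probes and give none a chromosome position, and none of the probe names matched the gene table of the wheat reference, so the files used here name a gene only for 6 probes, by a symbol. Another 41 probes are named by a sequence accession and 238 by a name beginning with ncbi_gi, and these were not matched to genes here. The largest increase among probes well above background on all arrays was that of wheat0130Contig548, whose log2 signal relative to the 75th percentile was -3.68 ± 0.01 in Chinese Spring and 2.43 ± 0.05 in the pistillody line (SD, n = 2). This was a 68.8-fold rise (log2 difference 6.10, SE 0.05, limma adjusted p = 1.48e-13). The next was wheat0130Contig1552, with a 32.8-fold rise from -5.29 ± 0.07 to -0.26 ± 0.07 (SD, n = 2; limma adjusted p = 3.45e-12). The largest decrease among probes well above background on all arrays was that of wheat0130Contig9317, from 4.10 ± 0.09 to -6.12 ± 0.12 (SD, n = 2), where the processed signal before scaling was 32800 and 38800 units in Chinese Spring against 30.9 and 33.1 units in the pistillody line. It amounted to a log2 difference of -10.22 (SE 0.07, limma adjusted p = 3.19e-14). The signal of wheat0130Contig6474 went from 2.68 ± 0.01 to -6.29 ± 0.15 (SD, n = 2), a log2 difference of -8.98 (limma adjusted p = 1.19e-13). The lowest signals called well above background on the pistillody arrays were 15.3 and 23.7 units. Under normexp with the 75th percentile the log2 differences were -8.54 for wheat0130Contig9317, -7.16 for wheat0130Contig6474 and 3.85 for wheat0130Contig1552.

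**Figure D3:**
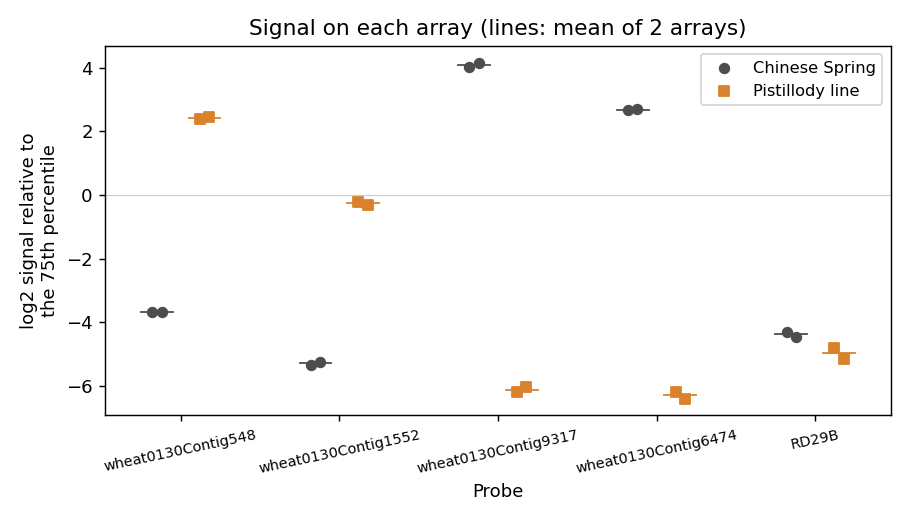
Log2 signal relative to the 75th percentile (vertical axis) of 5 probes on each of the 2 Chinese Spring arrays (circles) and 2 pistillody arrays (squares), with a line at the mean. The 2 leftmost probes were 68.8-fold and 32.8-fold higher in the pistillody line, the next 2 were lower by log2 differences of -10.22 and -8.98, and RD29B was lower by -0.60.

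Some transcripts were detected in only 1 of the lines. In Chinese Spring, 342 probes were well above background on both arrays and on neither pistillody array, and limma called 335 of them lower. The reverse held for 129 probes, and limma called all but 6 of these higher. Both sets were chosen by the same signals that limma tested, so its calls are no separate support for them. With signals below background set to each array's detection limit, taken as the lowest signal of any probe well above background there, the median probe of the first set was at least 2.69-fold higher in Chinese Spring, 125 probes were at least 4-fold higher and 49 at least 16-fold higher. The largest of these bounds was at least 3810-fold. In the reverse set the median probe was at least 1.73-fold higher in the pistillody line, 18 probes were at least 4-fold and 3 at least 16-fold higher. The largest bound, of a probe with a name beginning with ncbi_gi, was at least 174-fold, and 1 probe gave no bound above 1. These counts rest on detection calls that differ between arrays of 1 line. Without Chinese Spring replicate 1 the count of probes found only in Chinese Spring was 966, and without pistillody replicate 1 it was 879. The balance between the lines turned over without either of the other arrays. Without Chinese Spring replicate 2, 438 probes were found only in Chinese Spring and 751 only in the pistillody line, and without pistillody replicate 2 the counts were 352 and 572.

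Of the 47 probes named by a gene symbol or a sequence database accession (names beginning with ncbi_gi are counted apart), 18 were bright enough to test, and all 18 changed, 7 upwards and 11 downwards; adjusted over the list alone, the counts were also 7 and 11. Only 6 of these names are symbols, RD29A, RD29B, cor47, DREB2A, DREB2B and Wcor15, which are known as names of genes responding to cold, drought or abscisic acid, or of their regulators. RD29B was the only one of the 6 well above background. The log2 signal of the probe named RD29B fell from -4.38 ± 0.11 to -4.98 ± 0.24 (SD, n = 2), a 1.52-fold decrease (log2 difference -0.60, SE 0.14, limma adjusted p = 0.00304). Probes of the other 5, among them Wcor15, a cold-responsive gene of wheat, were not well above background on any array. Probe sequences were not used, so whether the 6 probes match wheat transcripts was not tested. A dim probe therefore does not show that a wheat gene was silent, nor RD29B that a wheat gene fell. The largest changes among the probes named by an accession were log2 differences of -2.35 and 1.48. The probe with the rise of 1.48 was well above background on only 3 arrays, and its Chinese Spring values had an SD of 1.49 (n = 2). Of the 238 probes with names beginning with ncbi_gi, 128 were tested, and 36 of these were higher and 49 lower.

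Most other probe names begin with a code or word shared by many probes, and no group of probes formed by these beginnings passed the test as a whole. An r before a name that goes on with wh was disregarded in forming the groups. In limma's camera test, which compares a group with all other probes, 0 of 41 groups of at least 50 tested probes shifted at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 3, and with an estimated correlation again 0 passed after adjustment. Probes whose names begin with whyf or rwhyf had the highest share of increases, with 260 of 650 probes higher and 126 lower, a median log2 difference of 0.10 and a camera adjusted p of 0.586. The probes named whoh or rwhoh followed with 294 of 748 higher and 151 lower. Probes with single names beginning with MUG had 308 of 1258 higher and 526 lower, a median of -0.09 and a camera adjusted p of 0.586. The group medians ranged from -0.12 to 0.14. In fry, which asks only whether a group moves on balance in 1 direction and not whether it differs from other probes, 18 of the 41 passed, and all 41 passed its mixed test for change in either direction.

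Decreases of at least 4-fold occurred in most of these groups. The largest groups, wheat0130Contig and MUGEST2003_23lib_Contig, held 303 and 141 of the 633, and some groups had none, such as whvs (0 of 219). Decreases outnumbered the increases of that size in 31 of the 41 groups and were outnumbered in 2. In some of the 31 the margin was small, such as 7 against 6 in the whyf and rwhyf probes. The share of probes at least 4-fold lower was 2.10% among all tested probes. It was slightly higher, at 2.51%, in the probes named wheat0130Contig (303 of 12066). It was lower in the single MUG names (0.556%, 7 of 1258) and in the whoh and rwhoh probes (0.535%, 4 of 748). The shares of these 3 groups differed from those of all other probes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjusted p of 0.00116, 0.000476 and 0.00961 over the 41 groups. No other group passed, although some smaller groups had higher shares, such as 4.35% in the whv group (7 of 161). Probes are not independent replicates in this test. The groups were also not matched on brightness. The probes at least 4-fold lower had a median log2 signal in Chinese Spring of -2.93, against -1.63 for all tested probes.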

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

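The block for the position on the slide and the source groups, formed by the beginnings of probe names, were chosen after the data were seen, as was keeping spots with outlier marks. The alternatives were run except those that need annotation (the gene lists and the arms of chromosome 7B) and those that need more than 1 slide or scan. The 4 printed probes and RD29B kept their direction and their side of the threshold in all 16 alternatives, with a largest adjusted p of 0.0203 for RD29B, whose log2 difference ranged from -0.77 to -0.29. The total count of changed probes and the counts in each direction stayed within 1.5 times the main counts throughout. Counts by size depended on the background correction. With normexp and the 75th percentile, 1393 probes changed at least 2-fold and 1211 were separated 2-fold, and with normexp and quantile normalization 1369 and 1191 did; the cause was not tested. At 3-fold in place of 2-fold, 1044 probes were separated. By fry, which does not compare a group with other probes and treats the correlation between probes differently, 18 source groups shifted, against 0 by camera; the cause was not tested. Leaving out each array in turn gave 15397 to 20425 changed probes, 7945 to 10798 higher, 7325 to 9627 lower, 2600 to 2841 changed at least 2-fold, 2372 to 2573 separated 2-fold, a ratio of 4-fold decreases to increases of 2.62 to 3.61, and 0 shifted source groups. The single array left in a line was then assumed to vary like those of the other line. The labels tie a replicate number to no shared plot or day, and the deviations of same-numbered arrays had a correlation of 0.09. With the replicate block 21582 probes changed, of which 19116 also changed without it. With the slide position as a block 17833 probes changed, of which 17548 also changed without it. Over all alternatives the median log2 difference of the tested probes lay between -0.03 and 0.05, and the share of increases among calls between 50.2% and 56.9%. Dim probes limit what can be seen: 7620 probes were not tested because neither line had both arrays well above background.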

Other observations

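The test of the missing chromosome arm was chosen only after the result it measures was seen; the values of the other tests were not known when the tests were set. The changes of probes whose names differ only by a leading r were correlated. In 1328 pairs with both probes well above background on all 4 arrays, the log2 differences between the lines had a Pearson r of 0.52 (95% bootstrap interval 0.45 to 0.59) and a Spearman rho of 0.53, each with a permutation p of 1e-04, the smallest that 10000 permutations can give (2e-04 after Benjamini-Hochberg adjustment over the 2 kinds of pair examined). Without the 2 pairs farthest from the median r was 0.56. Of the 522 such pairs with both probes called, 455 (87.2%) changed in the same direction. These correlations are across probes, which are not independent replicates.

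Decreases of at least 4-fold outnumbered increases by 3.04 to 1 (633 against 208), and the ratio was above 1 in every alternative run. Lower sensitivity of the pistillody arrays at the brightness of the decreased probes is argued against by 6003 other probes matched in Chinese Spring brightness. Their median log2 difference was 0.041 (95% interval 0.026 to 0.055), with probes changed at least 4-fold left out. A loss of sensitivity shared by all probes was removed by the scaling, so this value cannot show it. Single failed spots or probes are argued against as the whole cause only for decreased probes with a testable partner by name. There were 41 such partners (with or without the leading r), against 633 decreased probes. The median log2 difference of the 41 partners was -1.36 (95% interval -1.84 to -0.72), with 34 called lower and 2 called higher. Of the 41, 14 were themselves at least 4-fold lower, so pairs in which both probes fell entered from both sides. The interval treats the 41 as independent. The 8 testable partners of the increased probes had a median of 2.31. A candidate explanation is the missing long arm of chromosome 7B, whose genes the pistillody line cannot transcribe. A probe may also bind transcripts of the matching genes on other chromosomes, so a lost copy need not show. The ratio of 3.04 prompted the explanation by the missing arm and so is no evidence for it. That explanation stays open because no probe could be placed on a chromosome. The Aegilops crassa cytoplasm and the changed floral organs were not tested and stay open too. The missing arm and the cytoplasm occur together in the pistillody line, so a comparison of these 2 lines cannot tell their effects apart.

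A set of 878 probes was well above background on both arrays at the inner slide positions (Chinese Spring replicate 2 and pistillody replicate 1) and on neither outer array, against 2 probes the other way. The processed signals of these probes before scaling had a median log2 difference of 0.43 between inner and outer arrays, with medians of 21.2 and 16.8 units. The lowest signal called well above background was 15.8 and 15.3 units on the inner arrays and 24.0 and 23.7 on the outer ones. A difference in detection limit between the arrays may thus account for the split, in which each line had 1 array on either side. The probes were picked by the same detection calls, so their signal difference was partly set by the selection and is no separate test of this. Whether the slide position sets that limit was not tested, as there was only 1 slide.

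The array also holds 833 pairs of probes whose names differ only in p or m, and their changes correlated less closely. Over the 160 pairs with both probes well above background on all arrays, r was 0.16 (95% interval -0.06 to 0.36; permutation p 0.05, adjusted 0.05), Spearman's rho was 0.09 (permutation p 0.3, adjusted 0.3), and without the 2 farthest pairs r was 0.05, while 21 of the 28 pairs with both probes called (75%) changed in the same direction. Leaving out each array in turn moved r between 0.049 (without pistillody replicate 1) and 0.22 (without Chinese Spring replicate 1). Dimmer probes are argued against by 345 of the pairs with a leading r, matched on the brightness of the dimmer probe, which had an r of 0.55 (95% interval 0.45 to 0.63), higher by 0.39 (95% interval 0.15 to 0.64). Of all 833 pairs, 430 had only 1 probe well above background and 243 had neither. Detection of 1 probe was not associated with detection of the other (odds ratio 0.91, Fisher's exact test p = 0.521). For the pairs with a leading r the odds ratio was 4.67 (Fisher's exact test p = 2.18e-60). Whether p and m stand for opposite strands is not given in the sources used here and was not tested.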
